A study of Homo sapiens with 60 samples.

How the data were processed

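RNA from 60 HT29 samples was extracted with QIAzol, and strand-specific libraries were read as 100 bp pairs on an MGI sequencer, per the labels' protocols. The deposited table holds expected counts per gene, which the authors estimated with RSEM 1.3.3 after quality control with FastQC 0.11.9, trimming with Trim Galore 0.6.5 and alignment with STAR 2.7.3a to hg38, per the submitters' processing notes. The annotation release is not given in the sources used here. Expected counts share reads of near-identical copies by estimated probability, which makes pseudogenes, paralogs and readthrough genes uncertain. Of the values 7.7% to 9.78% per library were not whole, and they were rounded to whole counts. The table has 60675 gene identifiers, of which 34588 had a count above 0, and no entry that names no gene. Its 213 other columns of samples were not used here. Gene symbols came from a table of gene names, which held 56558 of the identifiers, and coordinates from GENCODE release 29 on GRCh38, the same assembly as hg38.

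Samples were grouped by extract and dose from their labels. Where an extract's IC20 was below 500 µg/mL, the labels describe doses at the IC20 and at 1/5 and 1/25 of it. The labels give the vehicle as 0.1% DMSO, and the series text gives 2% DMSO. Positive control compounds that the series text mentions were not analysed here. All titles carry the same batch letter. Replicates correlated at r of 0.9865 to 0.9933, and their counts differed beyond sampling noise (chi-square per degree of freedom of 2.47 to 26.17), so no library counted as a repeat of another.

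The 19 groups of 3 libraries (57 libraries) were fitted together with edgeR 4.0.16 in R 4.3.3, with TMM factors of 0.956 to 1.031, the filterByExpr filter, which kept 16445 genes, and the quasi-likelihood F test with 38 residual degrees of freedom. The common biological coefficient of variation was 0.05. A gene was called, and is said to have risen, fallen or changed, at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. There were 27 comparisons: each of 3 doses of 6 extracts with vehicle, high with low dose for 6 extracts, and the high doses of the 2 extracts of each of 3 sets. Log2 fold changes carry the standard error of the fit, and CPM are counts per M of the library total over the tested genes times its TMM factor, computed from the deposited counts, with the SD over 3 libraries.

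Gene lists were fixed before the data were examined, 34 in number with 689 entries, of which 686 matched an identifier. The 31 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists and the 6 comparisons of a kind. It asks whether a list moved further than other genes. With an estimated correlation, 5, 2, 9, 9, 13 and 6 lists were called against vehicle for Palmul-tang, Sibjeondaebo-tang, Poria, Atractylodes, Glycyrrhiza and Ginseng, in place of 14, 12, 17, 19, 18 and 17. Between high and low dose 11, 6, 9, 11, 13 and 12 were called in place of 14, 16, 16, 17, 17 and 14. The fry test gave a direction as a check. For the AhR list the camera test called a rise against vehicle with Palmul-tang, Atractylodes and Ginseng while the list medians were -0.01, -0.03 and -0.03, and with an estimated correlation its adjusted p was 0.0881, 0.025 and 0.0614. List members with no counts in a group were also set to the bound of 3 counts over that group, which moved 5 of 372 list medians, by at most 0.06.

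The genes named were chosen by a fixed rule. They are the 8 largest rises and 8 largest falls per high dose (5 and 5 for a direct comparison) among genes with a symbol, an adjusted p below 0.05, at least 5 CPM in the higher group, no overlap between the libraries of the groups and the same sign between high and low dose. Up to 3 called members per list with the largest changes were added. Genes shared by all 6 extracts and markers of other cell types were named after their values were seen. For Angelica, log2 ratios to the vehicle mean were computed with a prior count of 2 and no test. TMM factors were those of these and the vehicle libraries alone. Counted and named were only genes with at least 5 CPM in the high dose library or the vehicle mean. Their high dose CPM also had to lie outside the range of the vehicle libraries. Of these, the 6 highest and 6 lowest ratios of the same sign at all doses were named.

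The alternatives were RLE factors, no filter on low counts, DESeq2 1.42.0, a fit of the 6 libraries alone, the replicate number as a block, each library left out, and an estimated correlation for lists. Chosen after the data were seen were thinning of counts to 19.4 M per library, removal of GC content and length trends (99.3% of tested genes had a value), the mitochondrial share as a covariate and leaving out 3 libraries that lay apart on a principal component. The scripts were tested on simulated data. For the Glycyrrhiza high against low dose comparison with 16445 genes, 42%, 58%, 78% and 90% of genes changed 1.25, 1.5, 2 and 4-fold were recovered, with 5 false calls. For Ginseng high dose against vehicle the shares were 50%, 60%, 80% and 94%, with 10 false calls. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.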

Results

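Gene expression was measured by RNA sequencing in HT29 cells, a human colorectal adenocarcinoma line, after 24 h with herbal extracts used in traditional Korean medicine. The 60 libraries fell into 22 groups. Vehicle (DMSO) had 3 libraries. Palmul-tang and Sibjeondaebo-tang, multi-herb formulas given as water decoctions, and ethanol extracts of Poria, Atractylodes, Glycyrrhiza (licorice) and Ginseng each had 3 libraries at each of 3 doses. An ethanol extract of Angelica had 1 library per dose. The doses were 500, 100 and 20 µg/mL, except 350, 70 and 14 µg/mL for Glycyrrhiza and 320, 64 and 12.8 µg/mL for Angelica. The high doses of Glycyrrhiza and Angelica were thus their IC20 by the labels' dose rule. Total counts per library ranged from 19.31 M to 29.62 M with a median of 25.06 M, and the 3 vehicle libraries held 19.79 M to 20.88 M. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

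Each high dose was compared with vehicle, which asks what differed from cells given DMSO alone, and with the low dose of the same extract, which asks what depended on dose and uses no vehicle library. Sample names place the decoctions in set 8, Poria and Atractylodes in set 9, Glycyrrhiza and Ginseng in set 10 and Angelica in set 11, and give vehicle no set number. A difference from vehicle therefore cannot be separated from a difference between sets. Of 16445 tested genes, 2891 to 3684 differed from vehicle at the low dose of Palmul-tang (3362), Sibjeondaebo-tang (3291), Poria (3049), Atractylodes (3684) and Glycyrrhiza (2891), and 2133 at that of Ginseng. At the medium dose the numbers were 3474, 3302, 3382, 3410, 2154 and 1665 in the same order. Without vehicle library 3 the low dose numbers were 1891, 1833, 1824, 2341, 1654 and 1259, and the medium dose numbers 2011, 2008, 2015, 2086, 1379 and 853. With the 6 libraries alone they fell most at the low doses of Poria (1030) and Ginseng (760) and the medium dose of Ginseng (341), and with the mitochondrial share as a covariate at the low dose of Palmul-tang (1404) and the medium dose of Atractylodes (1325). The vehicle libraries also held a higher share of mitochondrial counts, 10.2% ± 1.4 (SD, n = 3), than any treated group of 3 libraries, whose means ran from 6.83% to 8.83%.

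**Figure D1:**
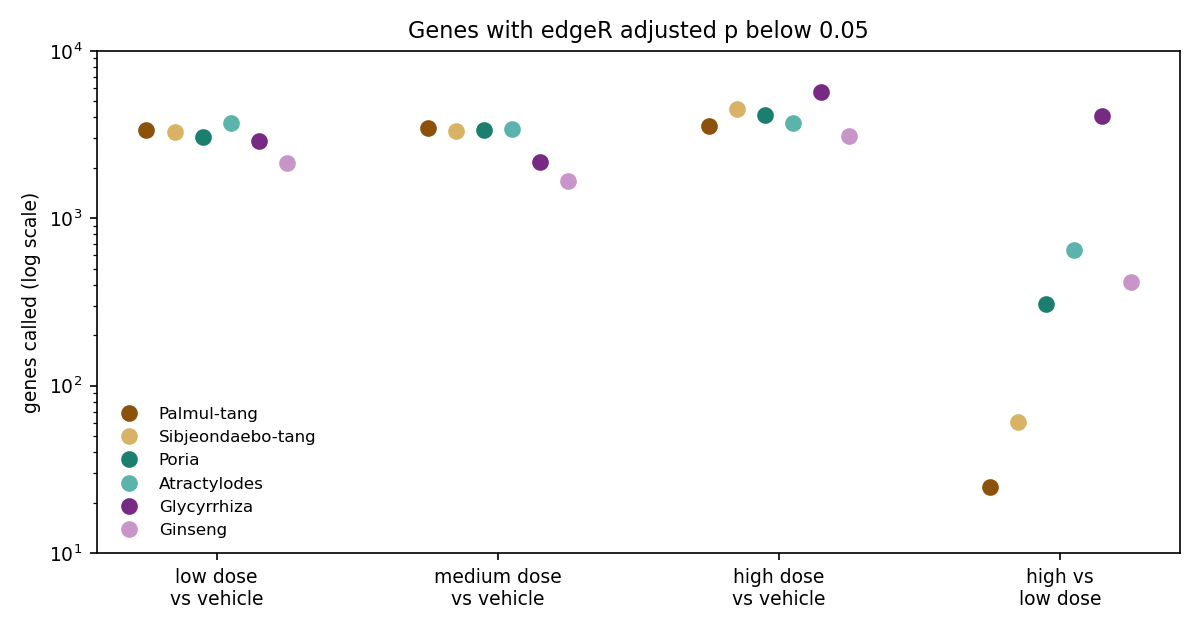
Genes with an edgeR adjusted p below 0.05 (vertical axis, log scale) for each extract at each dose against vehicle and for high against low dose, each point a comparison of 3 with 3 libraries. The counts against vehicle lie between 1665 and 5642 at every dose, and those between high and low dose run from 25 for Palmul-tang to 4096 for Glycyrrhiza.

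**Figure D2:**
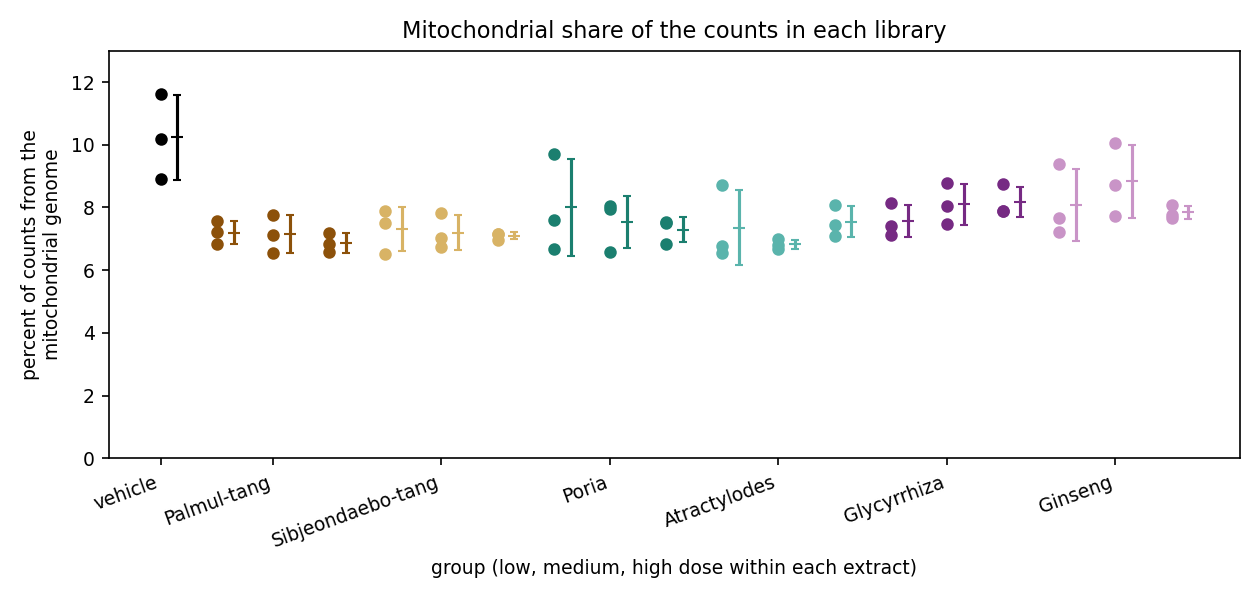
Percent of the counts of each library that came from mitochondrially encoded genes, by group, with points for libraries and bars for the mean ± SD of 3 libraries. Vehicle has the highest mean, 10.2%.

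Chemokine genes were higher than vehicle in the decoction groups. At 500 µg/mL Palmul-tang, CXCL1, which encodes a neutrophil-attracting chemokine (ENSG00000163739, GRCh38 chromosome 4, 73869393 to 73871242), was at 31.8 ± 3.04 CPM (SD, n = 3) against 1.62 ± 0.372 CPM in vehicle, a log2 fold change of 4.29 ± 0.14 (SE; adjusted p = 9.7e-28). CXCL8, which encodes interleukin-8, rose by 2.39 ± 0.08, from 5.91 to 31.1 CPM (adjusted p = 4.1e-27). CCL20, a chemokine of lymphocytes and dendritic cells, rose by 4.33 ± 0.33, CXCL3 by 2.41 ± 0.21 and PI3, the elastase inhibitor elafin, by 2.09 ± 0.14. Of the 22 tested genes of the NF-kB and inflammatory list, 17 rose and 0 fell against vehicle (19 and 0 adjusted over the list alone). The list median was 0.95, and the camera adjusted p was 2.37e-24. CXCL5 and SAA1, also on this list, had no counts in vehicle and 0.837 and 0.388 CPM at the high dose. At the medium and low doses CXCL1 was also above vehicle, by 4.11 (adjusted p = 4.4e-27) and 3.67 (adjusted p = 4.7e-24).

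Detoxification genes of the NRF2 list, targets of the transcription factor of the oxidative stress response, were also above vehicle with Palmul-tang. Against vehicle 17 of 25 rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 1.63e-10), among them AKR1C3 by 0.76 ± 0.09 and AKR1B10, aldo-keto reductases, the latter by 0.55 ± 0.06. The largest falls in named genes were CERS6-AS1 by 1.29 ± 0.27, the primate gene family member NPIPB13 by 1.14 ± 0.31 and the mitochondrial gene MT-ND6 by 0.88 ± 0.29. MUC17, a membrane mucin, fell by 0.85 ± 0.13, and 5 of 16 genes of the secretory lineage and mucin list fell (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00741). Of the 13 mitochondrially encoded genes 11 fell (12 adjusted over the list alone, median -0.72, camera adjusted p = 7.26e-08). That list had an adjusted p = 0.139 with an estimated correlation. With the mitochondrial share as a covariate MT-ND6 was at 0.09 and MT-ND1 at 0.23, neither called. The mitochondrial share of these libraries was 6.87% ± 0.31 (SD, n = 3) against 10.2% ± 1.4 in vehicle. NPIPB13, RN7SL1 (higher by 2.48 ± 0.84), BMS1P4-AGAP5 and DDX12P share sequence with near-identical copies and are uncertain. In all, 1930 genes rose and 1636 fell against vehicle. That total of 3566 was 2144 without vehicle library 3 and 1347 with the mitochondrial share as a covariate.

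Between the high and low doses of Palmul-tang, 17 genes rose and 8 fell. CXCL1 rose by 0.62 ± 0.09 (adjusted p = 0.00014), CXCL8 by 0.42 (adjusted p = 0.00035) and PI3 by 0.57 (adjusted p = 0.011), while CCL20, at 0.75 ± 0.21, did not pass (adjusted p = 0.16). The NF-kB list had 2 genes higher and 0 lower (9 and 0 adjusted over the list alone) and a camera adjusted p of 1.91e-07. The NRF2 list had 6 of 25 genes higher and 0 lower (20 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 1e-37). Of 31 interferon response genes 0 passed alone, with 4 lower adjusted over the list alone, and the list median was -0.19 (camera adjusted p = 1.99e-09). The total of 25 was 38 with DESeq2 and 115 without the filter on low counts. The unfiltered fit also gave smaller standard errors for abundant genes such as MT-ND1, so its counts are less certain. Leaving out a library gave 16 or fewer in every case: 16 without high 1, 11 without high 2, 16 without high 3, 13 without low 1, 16 without low 2 and 12 without low 3.

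With Sibjeondaebo-tang the same kind of genes were above vehicle. CXCL1 reached 30.6 ± 4.52 CPM (SD, n = 3), a log2 fold change of 4.23 ± 0.14 (adjusted p = 1.1e-27). CCL20 rose by 4.56 ± 0.32, CXCL8 by 2.49 ± 0.08, CXCL3 by 2.41 ± 0.21 and PI3 by 2.00 ± 0.14. In the NF-kB list 17 of 22 rose and 0 fell, both over all genes and adjusted over the list alone (median 0.91, camera adjusted p = 2.07e-20). SLC16A3, a lactate exporter in the glycolysis list, rose by 0.66 ± 0.07, and 10 of 17 genes of that list rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000277). Its adjusted p was 0.0925 with an estimated correlation. In the NRF2 list 13 of 25 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 2.74e-07). The NRF2 list had an adjusted p = 0.0646 with an estimated correlation. Among the named falls were CERS6-AS1, ETFRF1, a mitochondrial electron transfer regulator (by 1.15 ± 0.18), and VGLL1, a TEAD cofactor (by 0.86 ± 0.14). RN7SL1, RN7SL2, AGAP5, RPL12P16, RPS26P19, RAC1P2 and MTATP6P1 have near-identical copies and are uncertain.

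In total 2342 genes rose and 2157 fell with Sibjeondaebo-tang. The total of 4499 was 2994 without vehicle library 3, 2494 when the 6 libraries were fitted alone and 2205 with the mitochondrial covariate. Of 13 mitochondrially encoded genes 10 fell (12 adjusted over the list alone; camera adjusted p = 5.57e-06), with adjusted p = 0.22 with an estimated correlation and a mitochondrial share of 7.10% ± 0.11 (SD, n = 3). Between high and low dose 32 genes rose and 29 fell, among them CXCL1 (0.59, adjusted p = 2e-04), CXCL8 (0.49, adjusted p = 1.6e-05) and CCL20 (0.88, adjusted p = 0.029). The NRF2 list had 11 of 25 genes higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 1.23e-24), the NF-kB list 3 of 22 higher and 0 lower (7 and 1 adjusted over the list alone; camera adjusted p = 5.32e-05). Of 31 interferon genes 0 passed over all genes and 8 were lower adjusted over the list alone (median -0.22, camera adjusted p = 6.52e-12). The total of 61 was 9 for the 6 libraries alone, 109 with DESeq2, 341 without the filter, 95 without low library 1, 25 without low 2, 23 without low 3 and 29 without high 3.

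The high doses of Palmul-tang and Sibjeondaebo-tang, formulas that share most of their herbs, were then set against each other. The edgeR quasi-likelihood test called 0 genes, with 913 at an unadjusted p under 0.05. Without any difference a share of 0.05 of the 16445 tested genes would be expected there. DESeq2 called 3, the 6 libraries alone 1 and the test without the filter 148. The unfiltered fit also gave smaller standard errors for abundant genes, so its 148 is uncertain. CXCL1 was at 31.8 ± 3.04 and 30.6 ± 4.52 CPM (SD, n = 3 each), and AKR1B10 at 139 ± 7.22 and 129 ± 2.44 CPM. A count of 0 does not show that the formulas act alike.

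**Figure D3:**
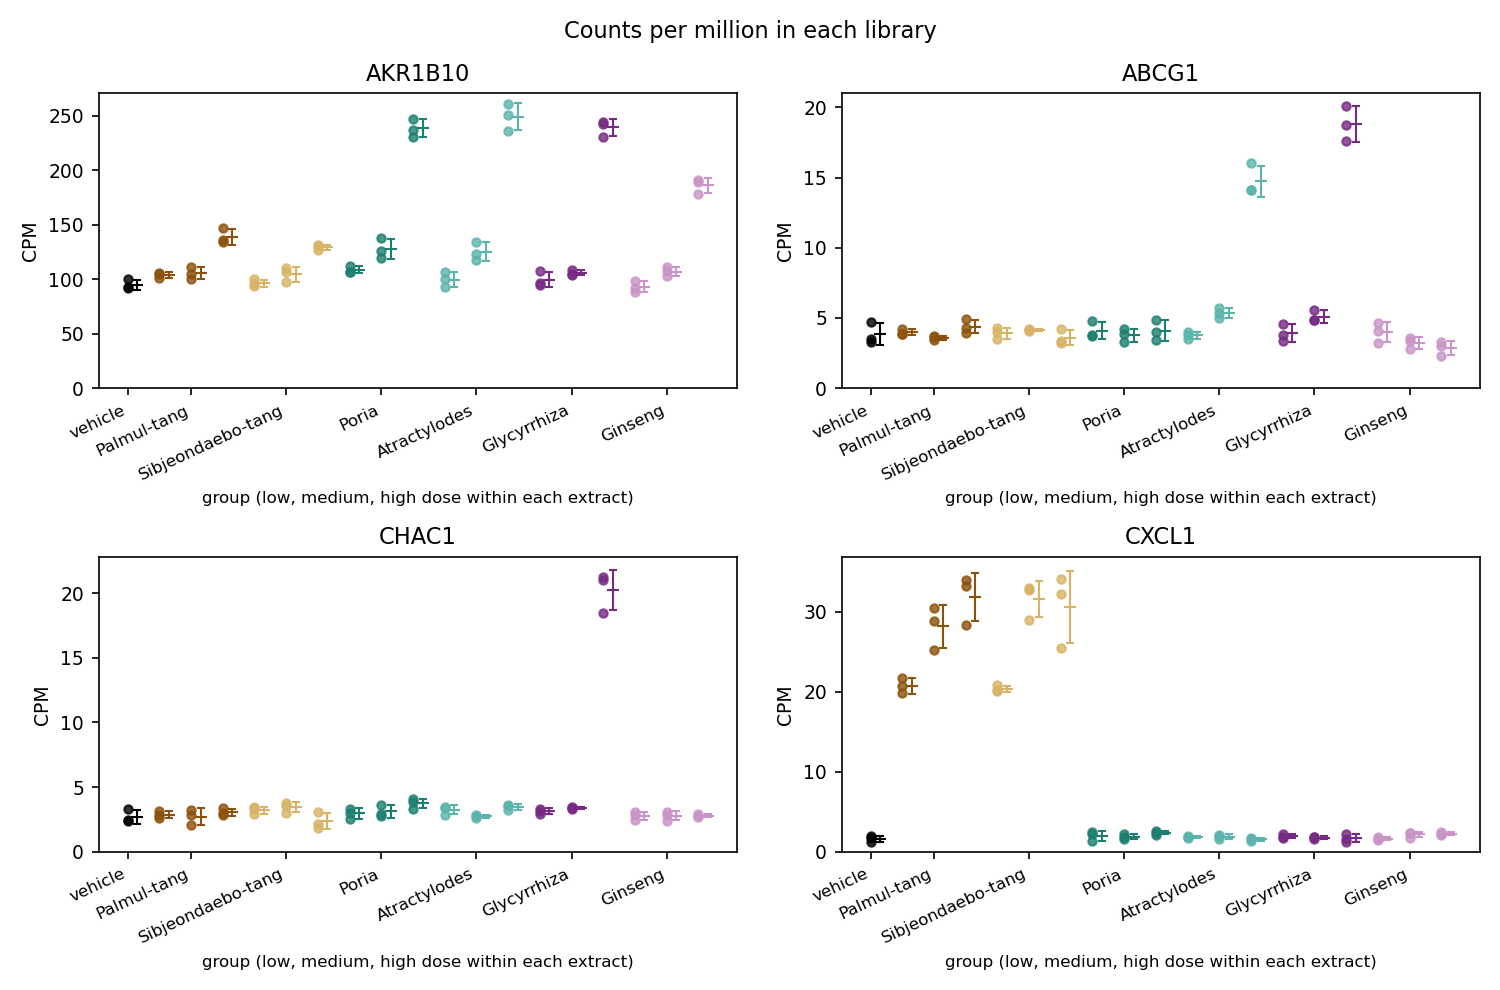
CPM of 4 genes in every library, with points for libraries and bars for the mean ± SD of 3, ordered within each extract from low to high dose. AKR1B10 is highest at the high doses (249 CPM with Atractylodes), ABCG1 with high-dose Atractylodes (14.7) and Glycyrrhiza (18.8), CHAC1 with high-dose Glycyrrhiza (20.3), and CXCL1 at all decoction doses (31.8 with high-dose Palmul-tang against 1.62 in vehicle).

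Aldo-keto reductase genes were above vehicle with Poria. At 500 µg/mL AKR1C2, which reduces steroid hormones and other ketones, reached 34.8 ± 2.09 CPM (SD, n = 3) against 12.1 ± 1.24 in vehicle, a log2 fold change of 1.52 ± 0.08 (adjusted p = 6e-20). AKR1B10 (ENSG00000198074, GRCh38 chromosome 7, 134527592 to 134541408) reached 238 ± 8.3 against 94.9 ± 4.65 CPM, a rise of 1.33 ± 0.06. AKR1C3 rose by 1.36 ± 0.09, AKR1C1 by 1.10 ± 0.06 and the aldehyde dehydrogenase ALDH3A1 by 0.98 ± 0.05. The AKR1C genes are close paralogs, so reads can be split between them. In the NRF2 list 24 of 25 genes rose and 0 fell (25 and 0 adjusted over the list alone; median 0.49; camera adjusted p = 1.74e-34). The AhR target list, genes of the aryl hydrocarbon receptor, had 3 of 7 higher (3 adjusted over the list alone; camera adjusted p = 1.96e-05). Those 3, ALDH3A1, UGT1A6 and NQO1, are also inducible by NRF2. MUC2, the main intestinal gel-forming mucin, fell by 0.80 ± 0.13 and REG4 by 0.65 ± 0.07. In the secretory lineage list 8 of 16 genes fell and 0 rose (8 and 0 adjusted over the list alone; camera adjusted p = 0.00106).

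CD200, an immune-regulatory surface protein, fell by 0.93 ± 0.13 with Poria, and SESN3, a stress-responsive sestrin, by 0.86 ± 0.14. In the list of FOXO and PI3K-AKT repressed genes 8 of 17 fell and 0 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.000124). The list of DNA replication genes had 21 of 34 higher and 0 lower (24 and 0 adjusted over the list alone; camera adjusted p = 1.52e-10), with the polymerase subunit gene POLD1 up by 0.47 ± 0.05. Of 13 mitochondrially encoded genes 11 fell (11 adjusted over the list alone; camera adjusted p = 1.04e-05), with adjusted p = 0.234 with an estimated correlation and a mitochondrial share of 7.3% ± 0.4 (SD, n = 3). Against vehicle 2211 genes rose and 1903 fell, and the total of 4114 was 2449 with the mitochondrial covariate. ATP6V1G2-DDX39B, a readthrough gene that overlaps its parent genes, was higher by 0.97 ± 0.22 and is uncertain.

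Between the high and low doses of Poria, 168 genes rose and 138 fell. AKR1C2 rose by 1.38 (adjusted p = 4.4e-19), AKR1B10 by 1.14 (adjusted p = 1.3e-20) and ALDH3A1 by 0.92 (adjusted p = 4.4e-19). In the NRF2 list 22 of 25 rose and 0 fell (25 and 0 adjusted over the list alone; camera adjusted p = 4.54e-84). The cystine transporter gene SLC7A11, which is on both the NRF2 and the ATF4 list, rose by 0.64. Of the ATF4 and integrated stress response list 7 of 24 genes rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 5.1e-09). CD200 fell by 0.55 (adjusted p = 0.012) and REG4 by 0.37 (adjusted p = 0.0014). The total of 306 was 84 for the 6 libraries alone and 519 without the filter. It was 147 without high library 1, 177 without high 2, 175 without high 3 and 169 without low 3.

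With Atractylodes the cholesterol efflux transporter ABCG1 had the largest rise over vehicle among the named genes. ABCG1 (ENSG00000160179, GRCh38 chromosome 21, 42199689 to 42297244) reached 14.7 ± 1.11 CPM (SD, n = 3) at 500 µg/mL against 3.84 ± 0.781 in vehicle, a log2 fold change of 1.93 ± 0.13 (adjusted p = 2e-16). ABCA1, another cholesterol transporter, rose by 0.70 ± 0.12, and MYLIP, which directs the LDL receptor to degradation, by 0.69 ± 0.08. In the LXR list, targets of the sterol-activated liver X receptors, 6 of 7 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 2.74e-07). Genes of cholesterol synthesis and its regulation went the other way. INSIG1, a sterol sensor partner, fell by 0.51 ± 0.08. ACSS2, an acetyl-CoA synthetase of the fatty acid synthesis list, fell by 0.80 ± 0.07. In the cholesterol synthesis and SREBP2 list 16 of 25 fell and 1, PMVK, rose (18 and 1 adjusted over the list alone; median -0.19; camera adjusted p = 5.72e-08). That call was lost with adjusted p = 0.158 with an estimated correlation.

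With Atractylodes AKR1C2 was above vehicle by 1.53 ± 0.08, AKR1B10 by 1.39 ± 0.06 and ALDH3A1 by 0.82 ± 0.05, with 23 of 25 NRF2 genes higher and 0 lower (24 and 0 adjusted over the list alone; camera adjusted p = 2.44e-29). The amino acid transporter SLC38A4 rose by 0.99 ± 0.17, and PDK4, an inhibitor of pyruvate oxidation, by 0.55 ± 0.11. VGLL1 fell by 1.53 ± 0.15, DSEL by 0.96 ± 0.20, ZNF608 by 0.90 ± 0.09 and the autophagy-linked TP53INP2 by 0.89 ± 0.10. In the secretory lineage list 6 of 16 fell and 0 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.000539), among them REG4 by 0.70 ± 0.07 and ATOH1, the secretory lineage transcription factor, by 0.66 ± 0.15. Of 13 mitochondrially encoded genes 9 fell (12 adjusted over the list alone; camera adjusted p = 2.45e-05), with adjusted p = 0.247 with an estimated correlation. Against vehicle 1965 genes rose and 1739 fell, and the total of 3704 was 2324 without vehicle library 3 and 1989 with the mitochondrial covariate.

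Between the high and low doses of Atractylodes, 318 genes rose and 331 fell. ABCG1 rose by 1.97 (adjusted p = 1.6e-17) and MYLIP by 0.57 (adjusted p = 2e-07), and the LXR list had 6 of 7 genes higher (6 adjusted over the list alone; camera adjusted p = 4.07e-14). ACSS2 fell by 1.14 (adjusted p = 9.4e-19). A fall of ACSS2 from low to high dose was called in at least 5 of the 6 extracts, so it was not particular to Atractylodes. In the cholesterol list 20 of 25 fell and 0 rose (22 and 0 adjusted over the list alone; median -0.32; camera adjusted p = 1.12e-34). The NRF2 list had 22 of 25 higher (24 adjusted over the list alone; camera adjusted p = 7.8e-70), and the ribosome biogenesis list 6 of 25 (16 adjusted over the list alone; camera adjusted p = 7.17e-13). The total of 649 was 303 for the 6 libraries alone, 380 without high library 1 and 405 without low library 3.

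The direct comparison of the high doses of Poria and Atractylodes, both of set 9, gave 88 genes higher with Poria and 73 lower. ACSS2 was higher with Poria by 0.86 ± 0.06 and the glycolytic enzyme ALDOC by 0.55 ± 0.07. ABCG1 was lower with Poria, with a log2 fold change of -1.84 ± 0.12 (4.10 against 14.7 CPM, adjusted p = 6e-16), as were ABCA1 (-0.82 ± 0.12), SLC38A4 (-0.77 ± 0.15) and the GABA receptor subunit GABRP (-0.76 ± 0.12). The total of 161 was 293 without the filter. It was 91 without Poria library 1, 107 without Poria 2, 74 without Atractylodes 2 and 99 without Atractylodes 3.

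**Figure D4:**
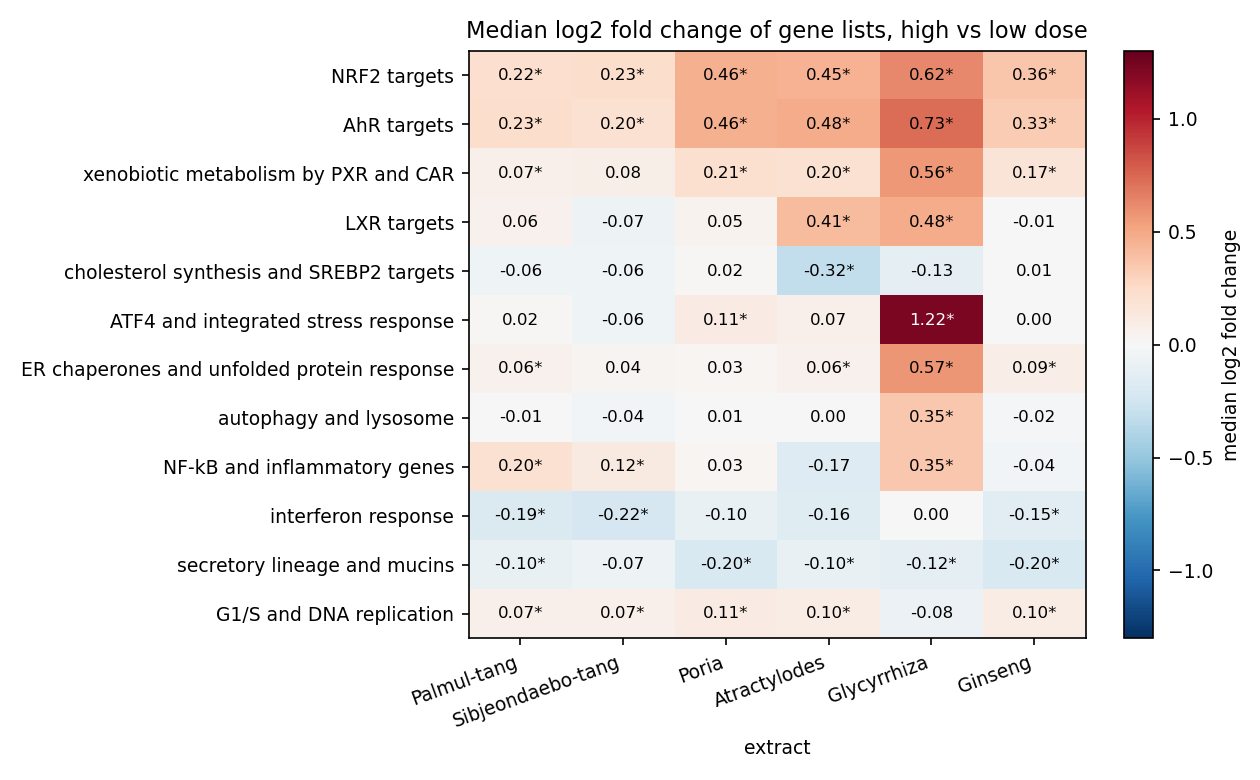
Median log2 fold change between the high and low dose of each extract (columns) for 12 of the fixed gene lists (rows), with a star where the camera adjusted p was below 0.05 with an estimated correlation. NRF2 medians run from 0.22 (Palmul-tang) to 0.62 (Glycyrrhiza), the cholesterol list is lowest with Atractylodes (-0.32), and the ATF4 list is highest with Glycyrrhiza (1.22).

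At the high dose Glycyrrhiza gave the largest counts of called genes of the 6 tested extracts, against vehicle and against the low dose, and genes of the integrated stress response were among those that rose. By the labels' dose rule 350 µg/mL was the IC20 of Glycyrrhiza, while the other tested extracts were given at 500 µg/mL. A response to inhibition at the IC20 therefore cannot be told apart from one particular to the extract. At 350 µg/mL CHAC1, a glutathione-degrading enzyme induced by ATF4 (ENSG00000128965, GRCh38 chromosome 15, 40952962 to 40956519), reached 20.3 ± 1.54 CPM (SD, n = 3) against 2.7 ± 0.539 in vehicle, a log2 fold change of 2.90 ± 0.13 (adjusted p = 2.5e-23). DDIT4, an inhibitor of mTOR signalling, rose by 2.18 ± 0.08 and ASNS, asparagine synthetase, by 1.99 ± 0.05, from 52.3 to 207 CPM. SLC6A9, a glycine transporter, rose by 3.36 ± 0.22, and the peptide hormone gene ADM2 by 2.83 ± 0.18. In the ATF4 list 23 of 24 genes rose and 0 fell, the same adjusted over the list alone (median 1.28; camera adjusted p = 2.09e-36). The list of endoplasmic reticulum chaperones had 20 of 20 genes higher, the same adjusted over the list alone (median 0.55; camera adjusted p = 8.26e-28). HERPUD1, of protein degradation at the reticulum, rose by 1.27 ± 0.05, and HSPA5, the chaperone BiP, by 1.00 ± 0.04.

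CYP1A1, a hydroxylase induced by the aryl hydrocarbon receptor, reached 26.2 ± 3.48 CPM (SD, n = 3) with Glycyrrhiza against 2.18 ± 2.51 in vehicle, where library 1 held 5.07 CPM and the others 0.61 and 0.85. The log2 fold change was 3.56 ± 0.28, and 7 of 7 AhR targets rose (7 adjusted over the list alone; camera adjusted p = 1.68e-10). In the NRF2 list 24 of 25 rose and 0 fell (25 and 0 adjusted over the list alone; camera adjusted p = 3.15e-25), with SLC7A11 up by 1.52 ± 0.07 and AKR1C2 by 1.47 ± 0.08. SLC7A11 is also on the ATF4 list. ABCG1 rose by 2.28 ± 0.12 and 7 of 7 LXR targets rose (7 adjusted over the list alone; camera adjusted p = 1.08e-06). The autophagy and lysosome list had 15 of 21 higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 3.15e-08), led by the cargo receptor SQSTM1, up by 1.23 ± 0.06. In the immediate early and MAPK feedback list 13 of 22 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 0.000106), with the phosphatase DUSP5 up by 1.41 ± 0.12. VEGFA, the angiogenic factor, rose by 0.97 ± 0.04, and FABP1, a fatty acid carrier of enterocytes, by 1.59 ± 0.21.

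Genes of intestinal stem and secretory cells fell with Glycyrrhiza. REG4 fell by 1.77 ± 0.08 (10.4 against 35.3 CPM), ATOH1 by 1.64 ± 0.18, and EPHB3, a Wnt-regulated receptor, by 0.68 ± 0.09. In the Wnt and intestinal stem cell list 10 of 14 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.40; camera adjusted p = 1.35e-07). The secretory list had 7 of 16 lower and 2 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.00193), the trefoil factor TFF2 being higher by 1.65 ± 0.29. CD200 fell by 2.24 ± 0.15, SLC14A1, a urea transporter, by 1.95 ± 0.15 and NEB, nebulin, by 1.93 ± 0.15. In the DNA replication list 12 of 34 genes rose and 7 fell (13 and 9 adjusted over the list alone), with a camera adjusted p of 0.91. In all, 3096 genes rose and 2546 fell against vehicle, of which 212 and 222 changed at least 2-fold. Of the 13 mitochondrially encoded genes 10 fell (11 adjusted over the list alone; median -0.56; camera adjusted p = 0.00134), with adjusted p = 0.369 with an estimated correlation.

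Between the high and low doses of Glycyrrhiza, 2306 genes rose and 1790 fell. CYP1A1 rose by 5.25 (adjusted p = 4.8e-18) from 0.674 CPM, CHAC1 by 2.69 (adjusted p = 6.4e-23), ABCG1 by 2.28 (adjusted p = 1.2e-20) and SLC7A11 by 1.77. The ATF4 list had 23 of 24 genes higher (23 adjusted over the list alone; median 1.22; camera adjusted p = 4.53e-46), the chaperone list 19 of 20 (20 adjusted over the list alone; camera adjusted p = 2.15e-35), the NRF2 list 24 of 25 (25 adjusted over the list alone; camera adjusted p = 5.01e-33) and the LXR list 7 of 7 (7 adjusted over the list alone; camera adjusted p = 6.39e-08). Of 31 interferon genes 8 rose and 8 fell (8 and 10 adjusted over the list alone), with a camera adjusted p of 0.87. CD200 fell by 1.88 and REG4 by 1.46. No alternative moved this total of 4096 by more than 1.5 times.

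With Ginseng AKR1C2 was above vehicle by 1.08 ± 0.08 at 500 µg/mL (25.5 against 12.1 CPM), AKR1C3 by 0.99 ± 0.09, AKR1B10 by 0.97 ± 0.06 (186 against 94.9 CPM) and MAP1A, a microtubule-associated protein, by 1.07 ± 0.14. In the NRF2 list 21 of 25 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 9.11e-21). VGLL1 fell by 1.34 ± 0.15, CD200 by 0.86 ± 0.13, REG4 by 0.80 ± 0.08 and ATOH1 by 0.73 ± 0.16, and 7 of 16 secretory genes fell (8 adjusted over the list alone; camera adjusted p = 0.000124). The DNA replication list had 20 of 34 genes higher and 0 lower (22 and 0 adjusted over the list alone; camera adjusted p = 6.62e-11). Of 13 mitochondrially encoded genes 6 fell (6 adjusted over the list alone; camera adjusted p = 0.000439), with adjusted p = 0.338 with an estimated correlation. EIF3CL, which shares nearly all its sequence with EIF3C, was lower by a log2 fold change of -3.21 ± 0.87 and is uncertain, as are CTAGE8, PKD1P1 and DDX12P, all higher. In all, 1697 genes rose and 1409 fell, and the total of 3106 was 2020 without vehicle library 3 and 1668 for the 6 libraries alone.

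Between the high and low doses of Ginseng, 212 genes rose and 203 fell. AKR1C2 rose by 1.24 (adjusted p = 9.8e-16), AKR1B10 by 1.00 (adjusted p = 4.7e-18) and ABCG2, a drug efflux pump, by 0.44 (adjusted p = 4.8e-09). The NRF2 list had 19 of 25 higher and 0 lower (25 and 0 adjusted over the list alone; camera adjusted p = 3.7e-51). ATOH1 fell by 0.74 (adjusted p = 0.0024) and IRF9, an interferon signalling factor, by 0.57 (adjusted p = 0.0033). Of 31 interferon genes 2 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 1.16e-06). Ginseng high 3 and low 3 and Poria low 1 lay beyond 20 on principal component 3, and the total of 415 was 208 without them. It was 107 for the 6 libraries alone, 207 without high library 1 and 246 without low library 3.

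Glycyrrhiza and Ginseng, both of set 10, were compared at their high doses of 350 and 500 µg/mL, so the doses differed. By the labels' dose rule only that of Glycyrrhiza was an IC20 below 500 µg/mL. With Glycyrrhiza 2189 genes were higher and 1641 lower. CYP1A1 was higher by 4.33 ± 0.30 (26.2 against 1.28 CPM), SLC6A9 by 3.72 ± 0.23, ADM2 by 2.99 ± 0.18, CHAC1 by 2.85 ± 0.13 and ABCG1 by 2.71 ± 0.13. NEB was lower, at -1.54 ± 0.15, as were CD200 (-1.38 ± 0.17), the pseudogene NPY6R (-1.13 ± 0.14) and the long noncoding RNA LINC00261 (-1.08 ± 0.13). ZBTB45P1 (-1.83 ± 0.59) is a pseudogene and uncertain.

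The high against low dose responses were compared across the 6 extracts, which asks whether they have a common part. AKR1B10, AKR1C2, ALDH3A1, GCLM, ME1, NQO1, UGT1A6, FLNA and SERPINB5 rose in all 6 and CD24 and SYTL2 fell in all 6, which makes 9 and 2 genes. GCLM, which encodes a subunit of the rate-limiting enzyme of glutathione synthesis, rose by 0.34 ± 0.06 with Palmul-tang and 0.94 ± 0.06 with Glycyrrhiza, and NQO1, a quinone reductase, by 0.20 ± 0.04 with Sibjeondaebo-tang and 0.55 ± 0.04 with Glycyrrhiza. Poria and Atractylodes shared 101 higher and 67 lower genes against 3.25 and 2.78 for independent lists of that size, with 0 in opposite directions. Atractylodes and Glycyrrhiza shared 199 higher and 174 lower genes, against 44.6 and 36, with 68 in opposite directions. Glycyrrhiza and Ginseng shared 134 and 125, against 29.7 and 22.1, with 42 in opposite directions. Over all 16445 genes the fold changes were weakly related. The mean Pearson correlation of the 15 pairs, across genes that are not independent replicates, was 0.073 (-0.014 to 0.208). Over genes with a mean of at least 5 CPM it was 0.315 (0.08 to 0.535), and the mean Spearman correlation was 0.189. Leaving out replicate 1, 2 or 3 gave 0.056, 0.043 or 0.039.

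The differences from vehicle at the low dose were common to the extracts to a larger extent. Called in the same direction in all 6 extracts were 1205 genes, 670 higher and 535 lower. Simulations of unchanged groups that share 3 simulated vehicle libraries gave 0, and independent lists 0.0211. The mean correlation of fold changes was 0.679 against 0.522 simulated, and the mean covariance 0.139 against 0.0489. The 3 vehicle libraries are too few to split, and the simulations hold no effects. The simulations also draw each gene independently, with a spread estimated over all groups. Shifts common to many genes of a real vehicle library are therefore absent from them. Part of each excess may thus come from sharing the vehicle libraries. Markers of fibroblasts, leukocytes and endothelium had 3, 4 and 4 tested genes, too few for a list test. With high-dose Glycyrrhiza LUM was higher by 1.04 ± 0.26, and with high-dose Palmul-tang and Sibjeondaebo-tang CD68, which many epithelial cells also express, was lower, at -0.72 ± 0.16 and -0.85 ± 0.17.

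Angelica had 1 library at each dose, so its differences have no replicate check and no p-value. Its CPM were scaled together with vehicle alone, which shifts vehicle values slightly from those above. At 320 µg/mL AKR1B10 was at 172 CPM against 94.0 ± 4.52 in vehicle (SD, n = 3; vehicle range 91.2 to 99.2), a log2 ratio of 0.87, and the ratio was 0.16 and 0.05 at the lower doses. MGAT2, a glycan-branching enzyme, had a log2 ratio of 0.89. MT-ATP8 was at 110 against 473 ± 120 CPM, a log2 ratio of -2.07, and MT-ND6 at -1.53. The other named genes were pseudogenes, small RNAs or readthrough genes with near-identical copies, such as RPS3AP26 (1.44) and FMC1-LUC7L2 (-2.12), and are uncertain. At the high dose 11 genes were higher and 37 lower by at least 2-fold. Counted were only genes with at least 5 CPM in that library or the vehicle mean and a value outside the vehicle range. The SD of the high dose log2 ratios over all 16445 genes was 0.419. Against 10000 random lists of matched size and expression, the NRF2 list median of 0.27 stood at percentile 100 at the high dose and at 89.04 and 81.79 at the lower doses. The mitochondrially encoded list (-0.84 at the high dose) stood at percentile 0 at all 3 doses. From the high to the low dose the interferon list stood at 0.03, 26.36 and 24.23, the DNA replication list at 100, 99.94 and 92.06, and the cholesterol list at 65.58, 100 and 99.76. There were 93 such percentiles in all, and extreme ones were common. The glycolysis list stood at 99.73, 99.88 and 99.38, and the secretory lineage list at 0.28, 2.96 and 0.58. Random lists do not keep the correlation between genes of a list, so a percentile near 0 or 100 in 1 library is weak evidence.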

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

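The tests of dose effect differences between extracts, of dose dependence, of constancy across doses, and those with the mitochondrial share, equal depth, GC content and length or 3 libraries removed were chosen after the data were seen.

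The effect of high against low dose differed between extracts of the same set, by an interaction test in edgeR. Poria and Atractylodes differed in 26 genes, 15 with a more positive effect in Poria and 11 with a more negative one. ABCG1 differed by -1.97 ± 0.18 (adjusted p = 6.1e-10) and ABCA1 by -0.74 ± 0.17, while ACSS2 differed by 0.91 ± 0.09, and the sterol synthesis genes LSS by 0.44 ± 0.05 and FDPS by 0.41 ± 0.06. Glycyrrhiza and Ginseng differed in 2126 genes, 1329 more positive and 797 more negative in Glycyrrhiza, with CYP1A1 at 4.17 ± 0.63, CHAC1 at 2.68 ± 0.20 and ASNS at 1.95 ± 0.07. Their high doses were 350 and 500 µg/mL, the first an IC20 by the labels' dose rule, so the extract and the dose changed together. Palmul-tang and Sibjeondaebo-tang differed in 0 genes by edgeR, and no other tool was run on this difference. At an unadjusted p under 0.05 there were 860 of 16445 genes, where a share of 0.05 is expected without any difference.

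Many genes differed from vehicle at the lowest dose of the 6 replicated extracts. A response that grows with dose argues for a median further move from low to high dose. For each extract this was read in genes called in 1 direction at the low dose of all 5 other extracts. Over these 7914 gene and extract pairs the move was 0, with a median low dose difference of 0.256. The choice favours differences common to the extracts and leaves out genes particular to 1 extract, so it bears only on the shared part. GC content with transcript length is not the whole cause, since the median ratio of corrected to uncorrected log2 fold change was 0.925. For the mitochondrial share of the libraries that ratio was 0.888. Its slope came from differences within groups, so the ratio bears on the gap to vehicle only if the same slope holds there. For library size the ratio was 1.001, but thinning keeps the expected fold change, so this value was set in advance and decides nothing. With the mitochondrial share in the model 48.8% of 18410 calls stayed, as the median absolute log2 fold change went from 0.24 to 0.21 and the median standard error from 0.06 to 0.07. A difference in culture, DMSO or library preparation between vehicle and treated samples that is unrelated to the extract may remain, and so may an effect already full at the low dose, since vehicle carries no set number.

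Chemokine and NF-kB target genes were above vehicle in both decoctions. GC content and transcript length did not account for this, with a ratio of 0.993. A difference between set 8 and vehicle that is the same at every dose is not the whole cause, because the 18 members called at the medium dose had median high against low dose changes of 0.31 in Palmul-tang and 0.258 in Sibjeondaebo-tang, with 15 and 16 members higher and 2 and 3 called. A constant part may still come from the set, since most of the CXCL1 difference from vehicle in Palmul-tang was already there at the low dose. CXCL8 also rose from low to high dose in at least 4 of the 6 extracts, so its rise was not limited to the decoctions. Cell-activating material that entered with the water decoctions, such as bacterial endotoxin, is a candidate explanation beside the herbs, and no test here bears on it.

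NRF2 target genes were higher at the high than at the low dose in all 6 extracts. GC content and transcript length left a ratio of 1.026, and without the 3 libraries apart on component 3 the members called in Poria and Ginseng numbered 36 in place of 41. The medium dose mean lay between the low and high dose means for 82.7% of 104 called members, but these were chosen for a gap between those means, so the share does not decide whether the response grows with dose. An activation of NRF2 by these extracts stays a hypothesis. No protein or NRF2 activity was measured. The pattern may also be a general response to electrophiles at high dose, by way of NRF2 or not, and so not particular to an extract.

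Splits of 3 against 3 libraries number 10, too few for a share under 0.05. In the list that follows each real count is given with the highest of the other splits, and 1 split of 10, the real one, reached the real count unless stated. Called genes at the high dose against vehicle were 2624 and 1 for Palmul-tang, 2494 and 0 for Sibjeondaebo-tang, 3698 and 0 for Poria, 3090 and 1 for Atractylodes, 4794 and 0 for Glycyrrhiza, and 1668 and 0 for Ginseng. At the medium dose they were 2247 and 1, 1579 and 0, 2262 and 0, 2998 and 1, 1591 and 0, and 341 and 1 in the same order. At the low dose they were 2758 and 0, 2416 and 0, 1030 and 0, 2326 and 0, 1965 and 1, and 760 and 0. Between high and low dose they were 21 and 3, 9 and 5, 84 and 1, 303 and 1, 3863 and 0, and 107 and 1. Poria against Atractylodes gave 231 and 3, and Glycyrrhiza against Ginseng 3081 and 0. Palmul-tang against Sibjeondaebo-tang gave 1 and 3, and 4 splits of 10 reached the real count. Called gene lists against vehicle were 14 and 9, 8 and 7, 17 and 12, 18 and 10, 18 and 9, and 15 and 9, and between high and low dose 14 and 10, 13 and 7, 16 and 8, 17 and 7, 20 and 10, and 13 and 9. Splits of mixed groups against vehicle thus had at most 1 called gene but up to 12 called lists. Each of these other splits mixes the groups unevenly, so it keeps part of the real difference and widens the spread within each side. Its counts therefore do not measure false calls of genes or lists. Fewer lists were called with an estimated correlation in every comparison. A list called only with the preset correlation is thus weak evidence by itself.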

How the results depend on the processing

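Equal depth, GC content and length, the mitochondrial covariate, the removal of 3 libraries and the settings of the dose effect differences were chosen after the data were seen. RLE factors, equal depth, and GC content and length moved no count of called genes by over 1.5 times. Depth of 19.31 M to 29.62 M counts limits genes near the filter, and causes were not tested below unless the construction shows them.

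Counts of called genes are given in the order Palmul-tang, Sibjeondaebo-tang, Poria, Atractylodes, Glycyrrhiza, Ginseng. With each library left out in turn, the high dose against vehicle ranged over 2144 to 3616, 2994 to 4362, 2767 to 4035, 2324 to 3756, 4443 to 5293 and 2020 to 2982. The medium dose ranged over 2011 to 3532, 2008 to 3255, 2015 to 3486, 2086 to 3484, 1379 to 2174 and 853 to 1813. The low dose ranged over 1891 to 3465, 1833 to 3325, 1824 to 3030, 2341 to 3712, 1654 to 2850 and 1259 to 2138. The lowest of each is without vehicle replicate 3, and the Sibjeondaebo-tang medium dose was also at 2131 without its own replicate 3. The Ginseng medium dose was at 1046 without vehicle replicate 2 and at 958 without its own replicate 2. High against low dose ranged over 11 to 16, 23 to 95, 147 to 253, 380 to 543, 3280 to 3605 and 207 to 420. Palmul-tang against Sibjeondaebo-tang stayed at 0, Poria against Atractylodes ranged over 74 to 114 and Glycyrrhiza against Ginseng over 3181 to 3289. Called lists ranged over 13 to 15, 9 to 12, 16 to 17, 18 to 21, 18 to 18 and 15 to 18 against vehicle, and over 13 to 15, 13 to 15, 13 to 19, 17 to 18, 17 to 20 and 14 to 17 between doses. Angelica genes changed 2-fold within the CPM and vehicle range limits ranged over 47 to 57. The mean fold change correlation, 0.073, ranged over 0.039 to 0.056.

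With the mitochondrial covariate Palmul-tang had 1347, 1557 and 1404 called genes at the high, medium and low dose, Sibjeondaebo-tang 2205, 1701 and 1549, Atractylodes 1989, 1325 and 1843, Poria 2449 at the high and 1752 at the medium dose, and Glycyrrhiza 1759 at the low dose. The log2 fold change of MT-ND6 turned to 0.09 in Palmul-tang and that of MT-ND1 to 0.23 in Palmul-tang, 0.11 in Sibjeondaebo-tang and 0.17 in Poria, as the covariate holds these genes. CYP1A1 turned to 0.52 in Sibjeondaebo-tang against vehicle without vehicle replicate 1, the library that held 5.07 CPM, and was -1.53 without vehicle replicate 2. The nuclear oxidative phosphorylation list turned direction in Sibjeondaebo-tang high against low dose without its high replicate 3, at an adjusted p of 0.473, against 0.000158 without its high replicate 2.

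With the 6 libraries alone, which leaves fewer residual degrees of freedom, the counts were 2247 for the Palmul-tang medium dose, 2494 and 1579 for the Sibjeondaebo-tang high and medium dose, 1030 for the Poria low dose, 2326 for the Atractylodes low dose, and 1668, 341 and 760 for the Ginseng high, medium and low dose against vehicle. High against low dose they were 9 for Sibjeondaebo-tang, 84 for Poria, 303 for Atractylodes and 107 for Ginseng, and Palmul-tang against Sibjeondaebo-tang gave 1. Without the filter, which tests 34296 genes, high against low dose gave 115 for Palmul-tang, 341 for Sibjeondaebo-tang and 519 for Poria, and the direct comparisons 148 for the decoctions and 293 for Poria and Atractylodes. That unfiltered fit also changed the error estimate of abundant genes. In Palmul-tang high dose against vehicle the standard error was 0.04 in place of 0.2 for MT-ND1, with the log2 fold change still -0.79. For MT-ND6 it was 0.05 in place of 0.29, at -0.88 in both. The added calls without the filter may come from this and are uncertain. DESeq2 gave 38 and 109 for high against low dose of Palmul-tang and Sibjeondaebo-tang and 3 between them. Without the 3 libraries apart on component 3, Ginseng high against low dose gave 208. With an estimated correlation the called lists against vehicle were 5 for Palmul-tang, 2 for Sibjeondaebo-tang, 9 for Poria, 9 for Atractylodes and 6 for Ginseng, and between doses 6 for Sibjeondaebo-tang, 9 for Poria and 11 for Atractylodes. The mean fold change correlation was 0.189 by Spearman rho and 0.315 over genes of at least 5 CPM.

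With the replicate number as a block, high against low dose gave 52 for Palmul-tang, 119 for Sibjeondaebo-tang, 465 for Poria and 623 for Ginseng, Poria against Atractylodes 247, and the dose effect difference of Poria and Atractylodes 49 in place of 26. The numbers were not taken to pair the libraries, since residuals of same-numbered libraries of a set correlated at a mean of 0.022 (-0.11 to 0.194). As a hint the other way, 27 of 57 libraries had a best partner of the same number, where 19 are expected for unrelated numbers, and the block raised every count of called genes that was not 0. Of 588 named gene results, 132 lost the call with the mitochondrial covariate, 48 with the 6 libraries alone, 23 without the filter, 21 with GC content and length, 20 at equal depth and 1 each with the block and RLE factors, in the same direction. With DESeq2 5 of 571 did, and without the 3 libraries apart 9 of 101. Each result was also fitted with libraries left out, 3528 fits in all, of which 309 lost the call in the same direction.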

Other observations

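Gene groups not described above were looked at after the data were seen. In Glycyrrhiza at the high dose KLF9 and TSC22D3, targets of the glucocorticoid receptor, rose by 0.99 ± 0.14 and 0.63 ± 0.06 against vehicle while HSD11B2, which inactivates cortisol, fell by 0.71 ± 0.10. In their list 6 of 9 genes rose and 2 fell (6 and 2 adjusted over the list alone), with a camera adjusted p of 0.114. SESN2 and GDF15, which are on both the ATF4 and the p53 list, rose by 1.10 ± 0.07 and 1.80 ± 0.08, and BTG2, an antiproliferative gene of the p53 list, fell by 1.05 ± 0.07. In the p53 list 9 of 23 genes rose and 4 fell (10 and 6 adjusted over the list alone), with a camera adjusted p of 0.0662. PDK4 and PLIN2, of fatty acid use and lipid droplets, rose by 1.16 ± 0.10 and 0.84 ± 0.11, and 9 of 15 genes of the PPAR list rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.000724). CYP2B6, a xenobiotic hydroxylase, rose by 1.16 ± 0.13, with 7 of 14 genes of the PXR and CAR list higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 5.46e-05).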
